A study of Drosophila melanogaster with 4 samples.

How the data were processed

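The series holds 4 libraries from white prepupae of Drosophila melanogaster: 2 of chromatin immunoprecipitated with an antibody against Pipsqueak and 2 of input DNA. Groups and replicate numbers were taken from the sample titles. The only processed data are a GFF3 list of 1661 peaks for the whole series, on FlyBase release 5 per the file headers. Per the submitters' processing notes, the tools were CASAVA (1.7.0.2 and 1.7.0.3), BWA and MACS2, and the genome build was BDGP5. Their settings, the peak threshold, the treatment of duplicate and multiply mapped reads, and whether replicates were pooled before peak calling are not given in the sources used here. The deposited list gives each peak's first and last base, counted from 1, and the score that the authors' peak caller gave it. The quantity behind the score is not named in the file. It was used to describe, rank and filter peaks within the list.

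Because the list names no replicate, none could be compared or left out, and nothing says whether replicates came from separate collections of animals. No read counts per library were used here, so depth is unknown, and intervals cover counting error only. The tests of promoter-proximal share, genomic feature classes, 18 sequence motifs including the GAGA element, and 25 gene lists had been planned before the data were examined. They need the genome sequence and annotation of release 5. The gene table at hand is from Release 6, whose coordinates do not match, so none of these tests was run, and genes and motifs are not analysed here. Peaks are therefore named by position: the rule, fixed before the data were examined, names the 20 peaks with the highest scores and the 3 fullest windows of 100 kb. The groups with the most peaks and the widest peak were named after their values were seen.

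Analyses used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and figures were drawn with matplotlib 3.10.9. Arms 2L, 2R, 3L, 3R and X entered the tests of position. Arm lengths were not at hand, so each arm was represented by the span from its first to its last peak, enlarged by (n + 1)/(n − 1) for n peaks. This departs from the planned use of sequence length. Observed counts were compared with span shares by two-sided exact binomial tests, with exact (Clopper-Pearson) 95% intervals and Benjamini-Hochberg adjustment. The choice of span means that peak-free sequence at arm ends does not count.

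Clustering was measured as the share of peaks with another peak centre within 10 kb. It was compared with 100000 placements of the same number of centres, drawn uniformly on the span of the same arm. Regions were formed by joining peaks separated by 1 kb or less, and larger groups by joining at 10 kb or less. Scores were compared between sets of peaks by two-sided permutation tests of the difference of medians with 100000 resamples. The midpoint of each span divided a centromere-proximal from a distal part, using the fact that the centromere lies at the high-coordinate end of X, 2L and 3L and at the low-coordinate end of 2R and 3R. To learn what the score measures, the Poisson mean whose −log10 upper-tail probabilities coincide with the most scores was sought between 5 and 150 reads, first within 0.005. Scores within 0.015 of such a step were then counted as on it, since a few common scores differed from it by slightly more than rounding. The comparisons of joined regions, of peaks with neighbours, of arm parts and of score steps were added after the data were seen.

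The procedures were tested on simulated data. With 1574 peaks placed uniformly, 4 of 100 simulated lists had any arm called, and with X at 1.5 times the density of the others it was called in 100 of 100. The arm test was not tried on grouped peaks, so its rate of false calls for such peaks is not known. The clustering test called 1 of 20 uniform lists and 20 of 20 lists with peaks placed in groups. In 3 of 3 simulated lists of 1661 scores the Poisson mean was recovered within 0.01. Alternatives were stricter score thresholds, other neighbour distances, joined peaks and placement within bins of 1 Mb.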

Results

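Chromatin immunoprecipitation followed by sequencing was used to map where Pipsqueak lies on the genome of Drosophila melanogaster white prepupae, the stage at which the larva stops moving and metamorphosis begins. Pipsqueak, encoded by psq, is a BTB-domain protein known to bind GAGA sequences in DNA. The animals came from the y; cn bw sp strain. There were 2 immunoprecipitated libraries, made with a rabbit polyclonal antibody against Pipsqueak, and 2 libraries of input DNA from the same stage, so the comparison was of antibody-bound chromatin with total chromatin. The result analysed here is the authors' list of peaks for the whole series. It gives a start, an end and a score for each peak and does not separate the replicates, so no spread between replicates and no depth per library can be given. All tests below treat peaks or groups of peaks as the units. Positions are those of FlyBase release 5. No gene annotation or genome sequence of that release was used here, so regions are named by position, and whether they lie in promoters, exons or introns, or contain GAGA elements, was not analysed here.

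Pipsqueak peaks numbered 1661 and covered 1185 kb in all. Of these, 1574 peaks lay on the 5 large arms, where they covered 1132 kb. Arm 3R held 385 peaks, 3L held 331, 2R held 326, X held 305 and 2L held 227. The small chromosome 4 held 3 peaks. The median peak on the 5 arms was 432 bp wide, with the middle 50% between 276 and 850 bp, and the widest was 8268 bp. The median score was 13.8, and the middle 50% lay between 10.1 and 25.8. The remaining peaks lay on the unplaced collections U (9 peaks) and Uextra (63 peaks), on the heterochromatic scaffolds 2RHet (2), 3LHet (2) and 3RHet (1), and on the mitochondrial genome (7).

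The strongest Pipsqueak peak lay on arm 2R at 16883347 to 16887799, with a score of 211. It was followed by a peak on 2L at 16349910 to 16354471, with a score of 206, and by 2 peaks on 3L. The first of these, at 13995104 to 14000145, had a score of 206, and the second, at 12797172 to 12800424, had a score of 197. Of the 20 peaks with the highest scores, 15 lay on the 5 arms: 4 each on 2R, 3L and 3R, 2 on 2L and 1 on X. The X peak, at 11047868 to 11049761, had a score of 157. These 15 peaks were between 1256 and 5369 bp wide, and 10 of them had at least 1 further peak within 10 kb. The other 5 of the 20 lay on Uextra (2), the mitochondrial genome (2) and U (1). The widest peak of the list, on 2R at 17594675 to 17602942, had a score of 126 and was not among the 20.

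Wide peaks had high scores. On the 5 arms the 394 widest peaks had a median score of 41.4 and the 395 narrowest a median of 9.68. Across the 1574 peaks, log2 width and log2 score correlated with Pearson's r = 0.84 and Spearman's rho = 0.80. Each had a permutation p of 1e-05, the smallest that the 100000 permutations can give, and this was the only relation of its kind computed, so the adjusted p is the same. Without the 2 peaks farthest from the median width, r was 0.84. This is a correlation across peaks, which are not independent replicates, and both quantities come from the same peak caller.

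Peaks were sparsest on arm 2L and, with every peak counted, densest on 2R. Among the 778 peaks with scores above 13.8 the ratio to expectation was highest on X (1.14, against 1.13 on 2R), and among the 390 with scores above 25.8 it was highest on 3R (1.20, against 1.11 on 2R). Arm 2L carried 10.4 peaks per Mb of its enlarged span, against 13.8 on 3R, 14.4 on 3L, 14.9 on X and 16.6 on 2R. The 227 peaks of 2L were 0.742 times the number expected from its span (exact 95% interval 0.654 to 0.836, adjusted p = 1.17e-06, two-sided exact binomial test with Benjamini-Hochberg adjustment over the 5 arms). The 326 peaks of 2R were 1.19 times the expected number (1.08 to 1.31, adjusted p = 0.00172, same exact test). Arms X, 3L and 3R had ratios of 1.07, 1.03 and 0.992, and none passed the exact test (adjusted p = 0.337, 0.639 and 0.884). The intervals cover counting error only, and the test takes peaks as independent, which the next comparison shows they are not. When peaks 1 kb or less apart were joined into a region, 2L kept its deficit with 151 regions and a ratio of 0.812 (exact test, adjusted p = 0.0186). The ratio of 2R was then 1.15 and no longer passed (exact test, adjusted p = 0.0823). With peaks 10 kb or less apart joined into groups, 2L too missed the threshold (ratio 0.821, exact test, adjusted p = 0.102).

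**Figure D1:**
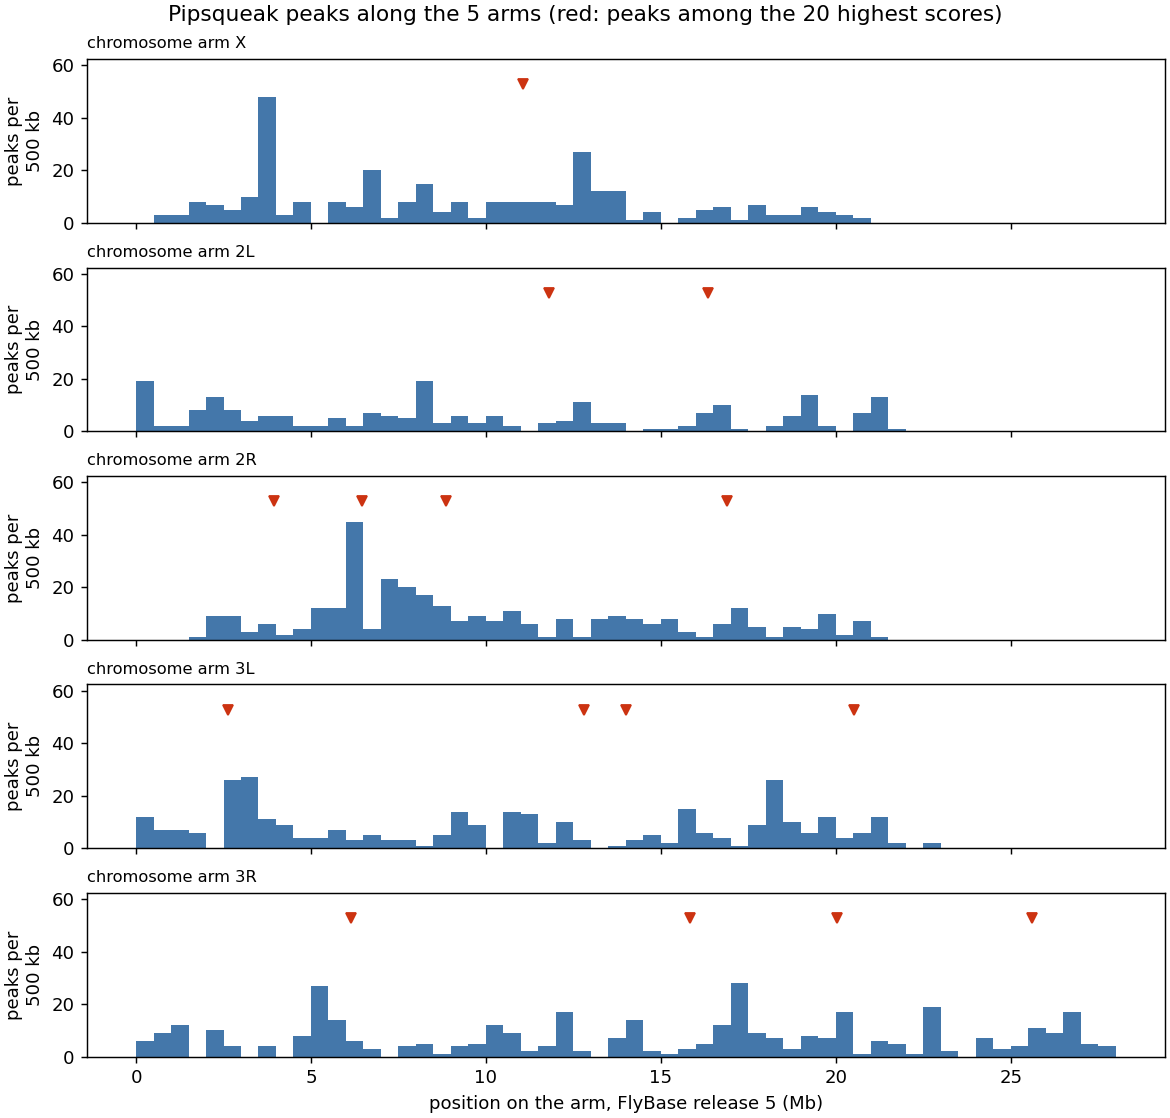
Number of Pipsqueak peaks in each 500 kb bin (vertical axes, linear and shared) against position in Mb on arms X, 2L, 2R, 3L and 3R (horizontal axis). Red triangles mark the 15 peaks on these arms that are among the 20 with the highest scores; the fullest bins are on X, with 48 peaks, and on 2R, with 45 peaks.

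Pipsqueak peaks came in groups. On the 5 arms 1198 of 1574 peaks, 76.1%, had the centre of another peak within 10 kb. When the same number of peaks was placed at random on each arm, the share was 24.8% ± 1.41 (SD over 100000 random placements), and the highest share of any placement was 30.9%. The two-sided p was 2e-05, the smallest that these placements can give. The share was much alike on each arm, from 75.1% on 3R to 77.0% on 2R. Part of this came from peaks parted by short gaps: 617 of the 1569 gaps between adjacent peaks, 39.3%, were 1 kb or less, and the shortest was 44 bp. Joining across such gaps left 957 regions, of which 646 held a lone peak. Of these regions 416, 43.5%, still had a neighbouring region within 10 kb, against 15.8% ± 1.58 at random placement (p = 2e-05 from 100000 placements, a permutation of positions, the smallest possible).

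**Figure D2:**
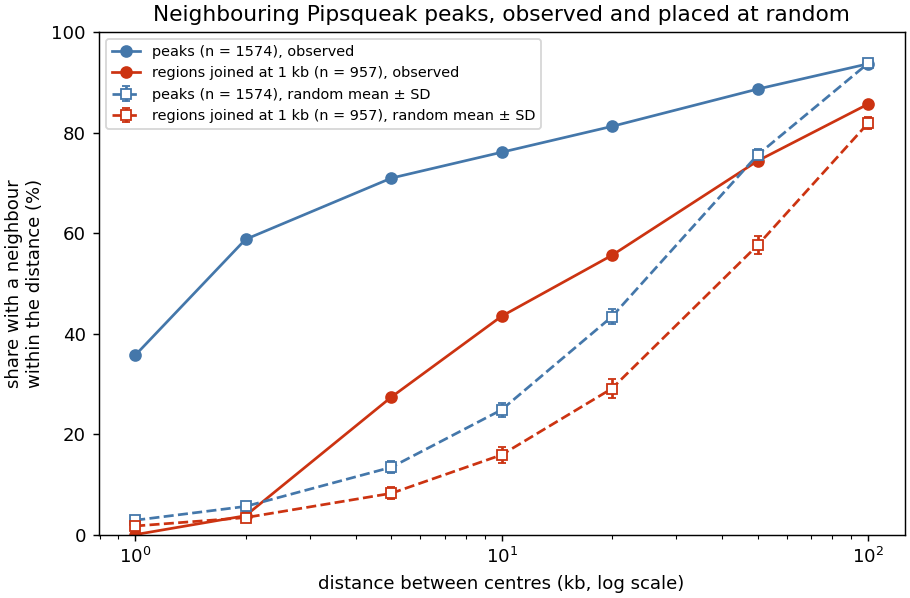
Share of peaks and of joined regions on the 5 arms with a neighbour (vertical axis, %) against the distance between centres (horizontal axis, kb, log scale). Joined regions lie more than 1 kb apart by construction, a limit that the random placements did not have. Filled points are observed values and open squares are means ± SD of 1000 random placements; at 10 kb the peaks stand at 76.1% and the regions at 43.5%, while at 100 kb the peaks, at 93.7%, no longer exceed random placement, at 93.8%.

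The largest groups lay on 2R, X, 3R and 3L. Joining peaks 10 kb or less apart gave 683 groups, of which 370 were lone peaks and 64 held 5 or more peaks. Those 64 groups held 556 peaks, 35.3% of those on the 5 arms. The group with the most peaks, 25, spanned 50.1 kb on 2R at 6421814 to 6471877 and contained the 2R peak at 6444514 to 6449624, with a score of 177. A group of 22 peaks spanned 22.1 kb on X at 3567758 to 3589884, with a highest score of 36.6. A group of 20 peaks spanned 24.2 kb on 2R at 7479523 to 7503683, where peaks covered 55.5% of the sequence. On 3R, 19 peaks lay between 17423710 and 17462430, and on 3L, 17 peaks lay between 2799242 and 2835924. The most continuous of these large groups was on X at 3663097 to 3676173, where 16 peaks covered 79.2% of 13.1 kb, with a highest score of 134.

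The 3 fullest windows of 100 kb held 39, 32 and 30 peaks. The first ran over X from 3570695 to 3670964 and took in peaks of both X groups named above. The second ran over 2R from 7479523 to 7539735, with a highest score of 97.6. The third ran over 2R from 6421814 to 6491924, with a highest score of 177. In 1000 random placements the fullest window held 7.75 peaks on average and never more than 11. Counted as joined regions, the same windows held 7, 8 and 12 regions. The random counts above are for peaks and were not computed for regions.

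Peaks with neighbours scored lower than isolated peaks. The 1198 peaks with another peak within 10 kb had a median score of 13.0 and the 376 isolated peaks a median of 16.3, a difference of -3.25 (permutation test, 100000 resamples, two-sided, p = 1e-05, the smallest possible). They were also narrower, with a median width of 418 bp against 476 bp. Among peaks of at most the median width on the 5 arms the difference was -0.815, with medians of 10.4 and 11.2 (permutation p = 0.00858). The strongest peaks of the 416 regions with a neighbour had a median of 15.7, against 20.1 in the 541 isolated regions (difference -4.47, permutation p = 0.00116). Those with neighbours were still narrower in both sets, so neither comparison removes width. Median widths were 275.5 against 287.5 bp for the narrow peaks and 669.5 against 723 bp for the regions. Peak scores did not differ detectably between arms. The arm medians ran from 13.4 on 2R to 14.7 on X, and in 5 permutation tests of each arm against the others the smallest adjusted p was 0.806.

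Along the arms, regions were unevenly spread on 2L and 2R, in opposite senses. In the centromere-proximal part of the span, taken up to its midpoint, lay 55 of the 151 regions of 2L, 36.4% (exact 95% interval 28.8 to 44.6, adjusted p = 0.00552, two-sided exact binomial test adjusted over 6 tests). On 2R it was 118 of 192, 61.5% (54.2 to 68.4, exact test, adjusted p = 0.00552). The 2R span starts at its first peak, at 1641938, so the peak-free sequence nearer the centromere was left out. The fullest 500 kb bins of 2R, with 45, 23 and 20 peaks, started at 6, 7 and 7.5 Mb. The 2R share therefore does not show a surplus next to the centromere. On 3L, 3R and X the shares were 43.3%, 44.2% and 45.7%, and none passed the exact test (adjusted p = 0.0914, 0.104 and 0.290). With peaks 10 kb or less apart joined, the share on 2R was 54.9% and did not pass (exact test, adjusted p = 0.298), while that on 2L was 37.6% (adjusted p = 0.0372). With each peak as a unit, 3L (42.9%, exact test, adjusted p = 0.0170) and X (40.3%, adjusted p = 0.00260) also passed, and the share on 2R was 67.5%. Over the 5 arms together it was 46.5% of 957 regions (exact test, adjusted p = 0.0657).

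The scores took a limited set of values. The 1661 peaks had 510 distinct scores, and the commonest, 8.99, was shared by 49 peaks. The scores of 1309 peaks, 78.8%, lay within 0.015 of the −log10 upper-tail probability of a whole number of reads under a Poisson law with a mean of 36.758. The best mean at least 1 read away matched 439 scores. Read on this scale, the 1280 matching peaks on the 5 arms stood at a median of 92 reads, 2.50 times the fitted mean, and the strongest, the 2R peak at 16883347 to 16887799, at 353 reads, 9.60 times. These read numbers are uncertain by 1, because the tail can be counted with or without the observed number, and the file does not say what they count, so they give no library depth. Scores off these steps made up 4.26% of the 305 X peaks (exact 95% interval 2.29 to 7.18) and 22.1% of the 1269 peaks on the 4 autosomal arms (19.9 to 24.5). With the narrower tolerance of 0.005, used first, these shares were 12.1% and 29.2%, so the X share depends on the tolerance. The difference at 0.015 was -17.9 percentage points (two-sided Fisher's exact test, p = 8.11e-16), and at 0.005 it was -17.0 percentage points. The Fisher test takes peaks as independent, which grouped peaks are not, and it was not repeated on joined regions.

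**Figure D3:**
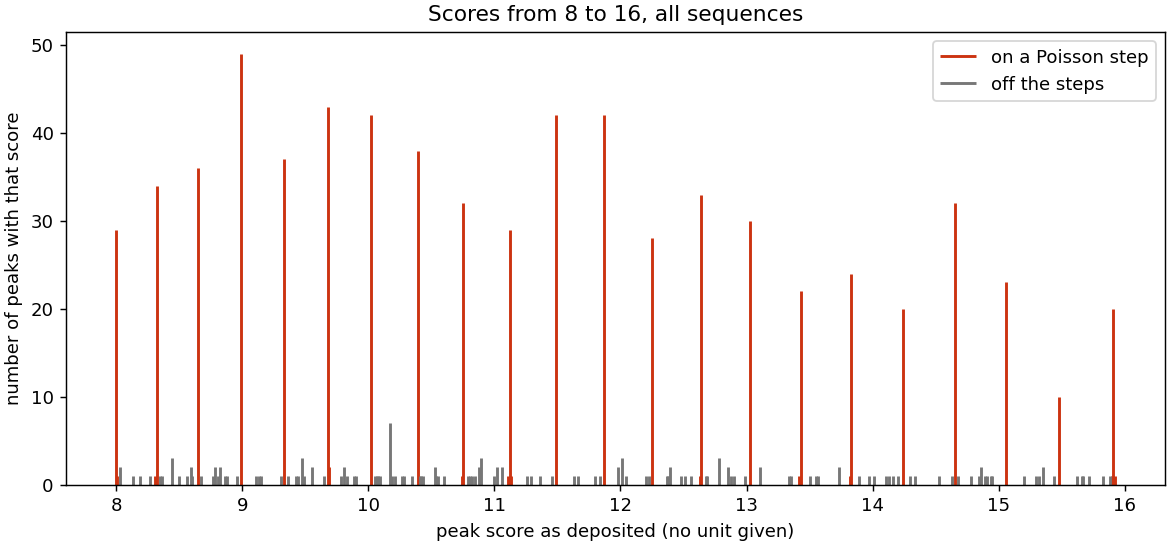
Number of peaks (vertical axis) at each deposited score between 8 and 16 (horizontal axis, no unit given), for peaks on all sequences. Red lines are scores within 0.015 of a Poisson step and grey lines are the others; 707 of the 864 peaks in this range lie on the steps.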

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

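Of the tests in this part, that of scores off the steps was chosen after the peak list had been examined but before its own result was seen, and that of the aligned gaps after its pattern was seen. Peaks outside the chromosome arms take no part in the comparisons of position, yet the list holds 7 on the mitochondrial genome, 9 on U and 63 on Uextra. The 72 peaks on U and Uextra had a median score of 39.6, against 13.8 on the 5 arms (difference 25.8, permutation test, adjusted p = 2e-05 over 4 tests, from the smallest p possible). The 7 mitochondrial peaks, between 6 and 14632, had a median score of 60.2 (difference 46.4, adjusted p = 0.00259, permutation test). They covered 91.7% of that stretch, so they are not 7 independent peaks, although the permutation test took them as such. The most covered stretch of the same length on the 5 arms, on X from 3663097, was covered to 70.8%. A block of 6 peaks on U, at 5288525 to 5303289, was covered to 94.2%. Uextra peaks had a median width of 342 bp against 432 bp on the arms, a difference of -90 bp (permutation test, adjusted p = 0.101).

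Explanations from the input were weighed for this pattern. A candidate explanation is sequence with a raised local background, as multi-copy or shared sequence would have. Then scores should leave the genome-wide Poisson steps more often there. They did for 53 of 79 peaks on U, Uextra and the mitochondrial genome, 67.1%, against 18.7% on the arms, a difference of 48.4 percentage points (Fisher's exact p = 1.17e-19). The shares were not matched on score. The Fisher test took peaks as independent, although those of the mitochondrial genome and of the U block are nearly continuous. From the lowest to the highest score quartile the share rose from 16.7% to 25.9% on the autosomal arms, but not on X (3.95% and 1.35%). Bound sequence in many copies would leave the steps as well, so the difference does not say why the scores were high. A further candidate, for the U block alone, is a copy of mitochondrial sequence sharing reads: its 5 gaps lay 61.9 bp on average from mitochondrial gaps under a common offset, against a median of 608 bp for gaps placed at random (permutation of gap positions, p = 0.00030, 10000 draws). That test was chosen after its pattern was seen, so its p-value is no independent support. Why peaks were called on these sequences, and whether Pipsqueak binds repeats, stays open, and no biological explanation was tested.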

How the results depend on the processing

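No paired analysis was possible because the peak list carries no replicate, and for the same reason no replicate could be left out. Tests of promoters, feature classes, motifs and gene lists, the placements matched on transcription start sites, and the expectation from transcription start sites were not run, for want of a release 5 annotation; the planned restriction to the 5 arms is the analysis as reported. Joined peaks, bins, width limits and tolerances were chosen after seeing the data. Clustering stayed above random placement in all 6 alternatives, with shares from 24.1% (390 peaks with scores above 25.8, random mean 6.88%) to 88.7% (50 kb, random mean 75.6%). The surplus of 2R peaks lost significance in all 4: 1.13 for the 778 peaks above a score of 13.8, 1.11 for the 390 peaks, 1.15 joined at 1 kb and 1.12 joined at 10 kb. The deficit of 2L did so only when joined at 10 kb (0.821). Neither 3L nor 3R passed in any setting, but with the 390 strongest peaks their ratios crossed 1, to 0.982 and 1.20. The cause was not tested. The share of units in the centromere-proximal part over the 5 arms passed only when joined at 10 kb (44.9%, exact test, adjusted p = 0.0372). The 3 windows fullest with every peak counted held 17, 12 and 12 of the 778 peaks. Of the 390 peaks they held 8, 5 and 4. Whether these windows stayed the fullest in those settings is not given here. The lower scores of peaks with neighbours kept their sign among peaks of at most the median width, but the difference shrank from -3.25 to -0.815 (permutation p = 0.00858). The higher scores on U and Uextra held without the U block (24.8), and the X difference in score steps was -17.0 percentage points with the tolerance of 0.005 used first, before 0.015 was adopted; the X share itself was then 12.1% in place of 4.26%, and the autosomal share 29.2% in place of 22.1%. Without depth per library, weak peaks cannot be told from absent ones by replicate.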

Other observations

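Of the tests in this part, placement within 1 Mb bins and the score quartiles were chosen after the peak list had been examined but before their own results were seen; joining at 1 kb, the Poisson steps and the X copy number were tested after the pattern was seen.

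The grouping of Pipsqueak peaks was set against a pair of technical explanations. Splitting of single enriched regions by the peak caller across gaps of 1 kb or less does not account for all of it. After joining across such gaps, 43.5% of regions still had a neighbour within 10 kb, above the 22.99% of the highest random placement. Broad differences in peak density along the arms do not account for all of it either: placing regions within their own 1 Mb bin gave a mean share of 17.4% and at most 23.9%. Splitting across gaps longer than 1 kb stays open, because the joining could not remove it. Within 2 kb, 3.76% of joined regions had a neighbour, against 3.39% at random. Within 5 kb it was 27.4%, against 8.22%. Joining kept regions more than 1 kb apart, a limit that the random placements did not have. The values at 2 kb therefore cannot show whether regions group at that distance. Uneven mappability or open chromatin at a finer scale stays open, since no genome sequence or accessibility data were used. The design names no biological contrast, so none was tested.

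The fixed score steps are consistent with a score that is −log10 of a Poisson p-value against a genome-wide background, since a mean of 36.758 matched 1309 of 1661 scores. X peaks left these steps in 4.26% of cases, against 18.9% on 2L, 17.8% on 3L, 24.4% on 3R and 26.1% on 2R. With the narrower tolerance of 0.005 the share was 12.1% on X and 29.2% on the autosomal arms together, a smaller contrast in proportion. A different range of scores on X does not account for this, because the share was lower on X in 4 of 4 score quartiles (permutation of arm labels within quartiles, p = 1e-05, the smallest possible). The permutation took peaks as independent, which grouped peaks are not. A candidate explanation is that X is present in fewer copies than autosomes in a collection of both sexes, so that local input there rarely exceeds the genome-wide mean. The difference of -17.9 percentage points was seen before this explanation was put forward, so it lends it no support. Input coverage was not analysed here and the labels do not give the sex of the animals. The explanation therefore cannot be told apart from other arm differences in the input.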
